A study of Mus musculus with 48 samples.

How the data were processed

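RNA from mouse hearts was sequenced after 20 weeks on a control or a high-fat diet, and per the labels the hearts were collected at 6 zeitgeber times (ZT, hours after the light phase begins) 4 h apart. The 48 libraries fall into 12 groups of 4. The groups come from the diet and time given for each sample. The labels carry no replicate numbers, so replicates were numbered in accession order, which only names them. The sources do not say outright that each library is a separate animal, so p-values measure the spread between these libraries.

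Per the labels' protocols, RNA was extracted with TriZol. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, STAR 2.7.3a (alignment), HTSeq 0.12.3 (counting) and DESeq2 1.28.1, with the mouse genome build GRCm38. The annotation release, the strand setting and the library kit are not given in the sources used here. The deposited values are raw counts of reads per gene, not normalized, and all 48 count columns matched a sample's label. The deposited table held 56246 genes and 5 rows that name no gene. Those rows took 28.1 to 36.6% of the reads per library: multiply aligned reads took 17.6 to 26.2%, ambiguous reads 5.11 to 6.46% and reads in no annotated gene 3.04 to 5.85%. They stayed out of library sizes and tests.

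Gene symbols were taken from a table of Ensembl identifiers. Of the identifiers, 54487 matched with their version and 55144 without it, and 1102 had no symbol. Coordinates are 1-based and come from GENCODE M21 on GRCm38. Multiply aligned reads were not counted, so near-identical genes (Acot1 and Acot2, the Scd genes, the alpha and beta globins, Hspa1a and Hspa1b) have uncertain levels. With the strand setting unknown, reads from overlapping genes cannot be told apart: 122 of the 293 genes followed by name overlap another annotated gene, and 25 overlap one with at least 0.1 of their counts, among them Dbp, Nr1d1, Ciart and Per3. Cpt1b lies inside a longer annotated gene and had a mean of 2.05 CPM.

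Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, which left 16642. Libraries were scaled by TMM (factors 0.909 to 1.14), and genes were tested with the robust quasi-likelihood F-test in 1 fit of all 48 libraries, with Benjamini-Hochberg adjusted p under 0.05 as a call. The median biological coefficient of variation was 0.166. Rhythms were fitted as a cosine and sine of a 24 h period within each diet, tested jointly in each diet and for the difference between the diets. An amplitude is the distance from mean to peak on the log2 scale. Diet effects (high fat minus control, log2, over all 6 times and at each time) and the contrast of ZT13, 17 and 21 against ZT1, 5 and 9 came from a fit of the 12 groups. Levels are CPM, counts scaled to the TMM-adjusted library size. Each group holds 4 libraries unless said otherwise, and each diet 24.

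The 36 gene lists (22 pathways, 14 cell types, 541 genes of which 517 were tested) were fixed before the data were examined, as were the design, the rule for naming genes and the first set of alternatives. List shifts were tested with camera in limma 3.58.1 on voom log2 CPM, with the preset correlation of 0.01 and with an estimated one. The share of rhythmic genes in a list was tested with Fisher's exact test, 2-sided. It takes the genes of a list as independent, so its p-values can be too small where they are correlated. Both camera and Fisher's test were adjusted over the lists with at least 3 tested members. "Adjusted over the list alone" means that the Benjamini-Hochberg adjustment ran over the list's members only. The lists were core clock, PPAR-alpha targets, mitochondrial beta-oxidation, triglyceride synthesis and lipid droplets, fatty acid synthesis, cholesterol synthesis, glucose uptake and glycolysis, glycogen metabolism, branched-chain amino acid catabolism, the nuclear-encoded respiratory chain, mitochondrially encoded genes, hypertrophy markers, extracellular matrix, interferon response, heat shock and chaperones, endoplasmic reticulum stress, oxidative stress response, insulin signalling, autophagy and proteolysis, glucocorticoid-responsive genes, ion channels and calcium handling, immediate early genes, and markers of cardiomyocytes, atrium, fibroblasts, endothelium, mural cells, macrophages, lymphocytes, neutrophils, erythroid cells, white and brown adipocytes, mesothelium, skeletal muscle and lung epithelium.

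Genes were named by rule among those past the threshold with a mean of at least 1 CPM, leaving out symbols of unnamed models: the 8 largest amplitudes peaking in each 12 h of the day (ZT0-12 and ZT12-24), up to 8 in each direction for the difference in rhythm, the 12 largest rises and 12 largest falls with diet among genes moving the same way at all 6 times, and the 3 largest rises and falls at each time. From each list up to 4 members with the smallest p were named, and every core clock gene. Some genes that these rules name are not reported here.

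Depth was 11.2 to 48.2 M counts in genes per library, with 12 libraries at 11.2 to 19.9 M and the other 36 at 21.4 M or more. The means were 25.3 ± 8.54 M in control and 25.9 ± 7.85 M in high fat (SD, n = 24 each). Every pair of replicates differed beyond counting noise, with a chi-square per degree of freedom of 14.4 to 590 over 5000 genes in 72 pairs, so no library was counted as a repeat of another. The libraries' numeric titles pass through the 6 times 3 times. The 3 runs of titles (13, 21 and 14 libraries, each with both diets) were treated as a possible batch. The first residual component of the 12-group fit held 27.0% of the residual variance, and the 7 libraries of lowest title number lie at one end of it (0.16 to 0.39, against -0.23 to 0.18 in the other 41).

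The scripts were tested on simulated counts with known changes over the same 16642 genes. For the diet effect over all times, 67.2% of genes changed by 0.3 log2 and 90.9% of those changed by 1 log2 were recovered. For an amplitude of 0.3 or 1 in control alone, recovery was 56.7% and 95.5% for the control rhythm, and 31.3% and 80.3% for the difference between diets. For a diet effect at ZT1 alone it was 43.3% at 0.6 log2 and 89.4% at 2 log2. For a step of 0.3 or 1 log2 between ZT9 and ZT13 it was 35.8% and 83.3%. False calls were 2.23 to 6.25% of calls. The simulated genes were drawn independently, without a residual component or batch shared between genes, so these rates may not hold for the real libraries.

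Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE scaling in edgeR, no filter on low counts, the run of titles as a covariate, fits of fewer libraries (1 diet or 1 time alone), a test of any difference between the 6 times, and leaving out each library in turn. Alternatives added after the data were seen were covariates for lower depth, the share of reads in no gene, atrial markers and the first residual component, and fits without the 12 lower-depth libraries or without the 7 libraries of lowest title number. The contrasts were also repeated on up to 100 regroupings of the libraries.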

Results

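Messenger RNA was measured in 48 mouse heart libraries to ask how obesity from a fatty diet changes the heart's differences between day and night. Control and high-fat hearts were taken at ZT1, ZT5, ZT9, ZT13, ZT17 and ZT21, with 4 libraries for each diet and time. Each library held 11.2 to 48.2 M counts in genes, and 16642 genes were expressed well enough to be tested. Feeding times, body weights and sex are not given in the labels. Over the libraries the Y-linked gene Ddx3y was at 53.1 to 89.4 CPM and Xist at 0.167 to 2.63 CPM, as in male hearts.

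The first question was which genes of the control heart follow a daily rhythm. In control hearts the clock genes Dbp and Arntl had the largest amplitudes of the genes named. Dbp, a transcription factor that drives clock output genes (ENSMUSG00000059824.12, chromosome 7, 45705088 to 45710203), rose from 7.98 ± 3.02 CPM at ZT1 to 151 ± 9.32 CPM at ZT9 (SD, n = 4 each). Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116.8, chromosome 7, 113207465 to 113314126), went the other way, from 21.3 ± 5.00 CPM at ZT1 to 1.75 ± 0.63 CPM at ZT9. Their amplitudes were 2.19 ± 0.14 (SE) log2 for Dbp, with a peak at ZT9.78, and 2.10 ± 0.11 for Arntl, with a peak at ZT23.6 (edgeR adjusted p = 1.6e-14 and 5.4e-18, n = 24). Among other genes peaking in ZT0-12, Spon2, a secreted matrix protein, reached an amplitude of 1.88 ± 0.15, the repressor Nr1d1 1.46 ± 0.10. The clock repressor gene Ciart reached 1.35 ± 0.12, the period genes Per1 and Per3 1.32 ± 0.13 and 1.22 ± 0.07, the collagen gene Col5a3 1.01 ± 0.05 and the magnesium transporter gene Slc41a3 0.99 ± 0.07. Among those peaking in ZT12-24 were Per2 (1.52 ± 0.10), the stress-induced actin-binding gene Fam107a (1.44 ± 0.16) and Mthfd1l of mitochondrial one-carbon metabolism (1.30 ± 0.14). Others there were Hif3a of the oxygen response (1.29 ± 0.22), the heat shock gene Hspa1a (adjusted p = 0.0028), the transcription factor gene Zbtb16 (1.26 ± 0.13) and Slc4a1, the anion exchanger of red blood cells (1.25 ± 0.36). In all, 2301 of 16642 genes (13.8%) were called rhythmic in control hearts, with a median amplitude of 0.26 log2, and 1137 peaked in ZT0-12 and 1164 in ZT12-24. The calls of Hspa1a and Slc4a1 were lost when 1 library was left out (adjusted p up to 0.101 and 0.186 over all alternatives).

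**Figure D1:**
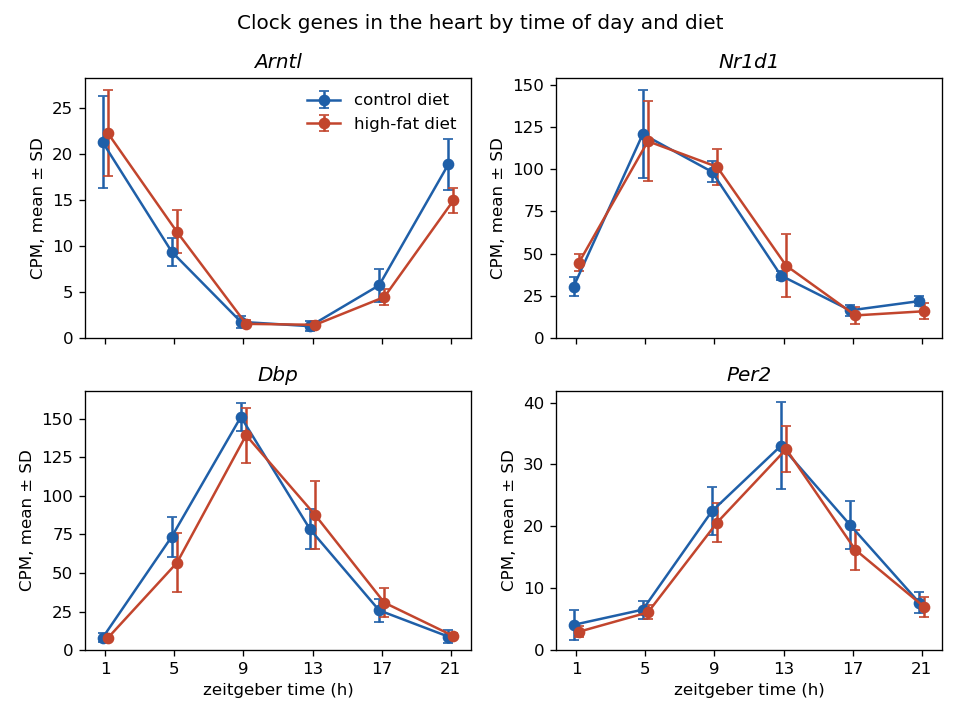
Level of 4 clock genes (CPM, mean ± SD, n = 4 libraries per point) against zeitgeber time in hours, for control (blue) and high-fat (red) hearts. The curves of the diets lie close together: Dbp stood at 151 ± 9.32 CPM at ZT9 in control and 139 ± 17.8 CPM in high fat.

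The same clock genes cycled in high-fat hearts. Dbp went from 7.83 ± 0.99 CPM at ZT1 to 139 ± 17.8 CPM at ZT9, and Arntl from 22.3 ± 4.63 CPM at ZT1 to 1.53 ± 0.39 CPM at ZT9 (SD, n = 4 each). The amplitudes were 2.15 ± 0.14 for Dbp, 2.11 ± 0.11 for Arntl, 1.70 ± 0.14 for Spon2 and 1.67 ± 0.10 for Nr1d1. They were 1.64 ± 0.10 for Per2, 1.33 ± 0.12 for Ciart, 1.25 ± 0.16 for Fam107a and 1.23 ± 0.13 for Mthfd1l and for Per1. They were 1.19 ± 0.07 for Per3, 1.04 ± 0.12 for the clock activator gene Npas2 and 0.97 ± 0.07 for Slc41a3 (SE, n = 24). Genes named in high fat that did not pass in control were Hba-a2, an alpha globin gene (1.61 ± 0.36, against 0.48 ± 0.36 in control) and the beta globin gene Hbb-bt (1.16 ± 0.30, against 0.84 ± 0.30). So was Angptl4, which encodes an inhibitor of lipoprotein lipase (1.26 ± 0.24, against 0.50 ± 0.26). The test of a different rhythm was not passed by Hba-a2, Hbb-bt or Angptl4. The noncoding RNA Bc1 passed in both (1.19 ± 0.23 in high fat, 1.10 ± 0.23 in control). In all, 1323 genes (7.95%) were called rhythmic in high fat, with a median amplitude of 0.26 log2, and 726 peaked in ZT0-12 and 597 in ZT12-24. Hbb-bt lost its call in 7 of 11 alternatives. The score of erythroid markers varied widely within groups, as from 4.90 to 8.66 mean log2 CPM in highfat_ZT13.

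Fewer genes were called rhythmic in high fat (1323) than in control (2301), and the order turned round without 7 of the libraries. The 7 libraries of lowest title number (3 control and 4 high fat, all at ZT21, ZT1 or ZT5) had more reads in no annotated gene (median 4.51%, against 3.61% in the other 41) and higher scores of the respiratory chain genes (median 8.83 against 8.39 mean log2 CPM). Without them, 2094 genes were called in control and 2236 in high fat. Within the 3 runs of titles the control and high-fat counts were 3074 and 4128, 1304 and 1129, and 180 and 38, on 13, 21 and 14 libraries. In the run of 13 the libraries at ZT21, ZT1 and ZT5 are those same 7, so time of day there cannot be told apart from what sets the 7 apart.

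Most genes called in both diets peaked at about the same hour. There were 909 such genes, against 183 expected of independent lists, which is 39.5% of the control list and 68.7% of the high-fat list. Their peaks lay within 2 h of each other for 83.7%, with a median absolute shift of 0.897 h. Both lists came from 1 fit with 1 estimate of spread per gene. They are therefore not independent, and part of the overlap can be built in. The 7 libraries of lowest title number lie at ZT21, ZT1 or ZT5 in both diets. What they add to the overlap and to the shared peaks was not tested. Of the 1806 genes called in 1 diet alone, 311 had an unadjusted p under 0.05 for the difference itself. These genes were chosen on the same libraries for passing in 1 diet alone, which favours a difference. Over all 16642 genes 664 had such a p, where chance would give 832.

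Over all genes, 1 passed the test for a different rhythm. Pdk4, the kinase that shuts off pyruvate dehydrogenase and so spares glucose (ENSMUSG00000019577.6, chromosome 6, 5483351 to 5496309), peaked at ZT10.3 in control (amplitude 0.65 ± 0.18) and at ZT22.4 in high fat (0.87 ± 0.18; SE, n = 24, edgeR adjusted p = 0.0468). It stood at 161 ± 42.97 CPM in control and 1292 ± 101 CPM in high fat at ZT21, but at 388 ± 213 and 281 ± 88.0 CPM at ZT9 (SD, n = 4 each). Ucp3, the gene of a mitochondrial uncoupling protein of muscle (ENSMUSG00000032942.14, chromosome 7, 100472990 to 100486432), went from 33.1 ± 5.98 CPM in control to 132.7 ± 23.5 CPM in high fat at ZT21 and from 95.5 ± 34.6 to 62.1 ± 22.8 CPM at ZT9. Angptl4 (ENSMUSG00000002289.16, chromosome 17, 33773750 to 33781830) went from 7.86 ± 8.82 to 83.6 ± 15.9 CPM at ZT21 and from 12.4 ± 5.63 to 10.6 ± 5.14 CPM at ZT9. For these last genes the difference in rhythm did not pass adjustment over all genes (edgeR adjusted p = 0.173 for Ucp3 and 0.294 for Angptl4, unadjusted 6.2e-05 and 1.4e-04). Nor did Ucp3 pass as rhythmic in high fat (0.30 ± 0.16, adjusted p = 0.443; 0.75 ± 0.16 and 9.5e-04 in control) or Angptl4 in control (adjusted p = 0.456). The Pdk4 call was lost in 5 of 10 alternatives and in 30 of the 48 fits without 1 library (adjusted p up to 0.148), and the gene count was 0 to 5 over single left-out libraries. An unadjusted p under 0.05 was met by 664 genes, where chance would give 832, and DESeq2 called 5.

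**Figure D2:**
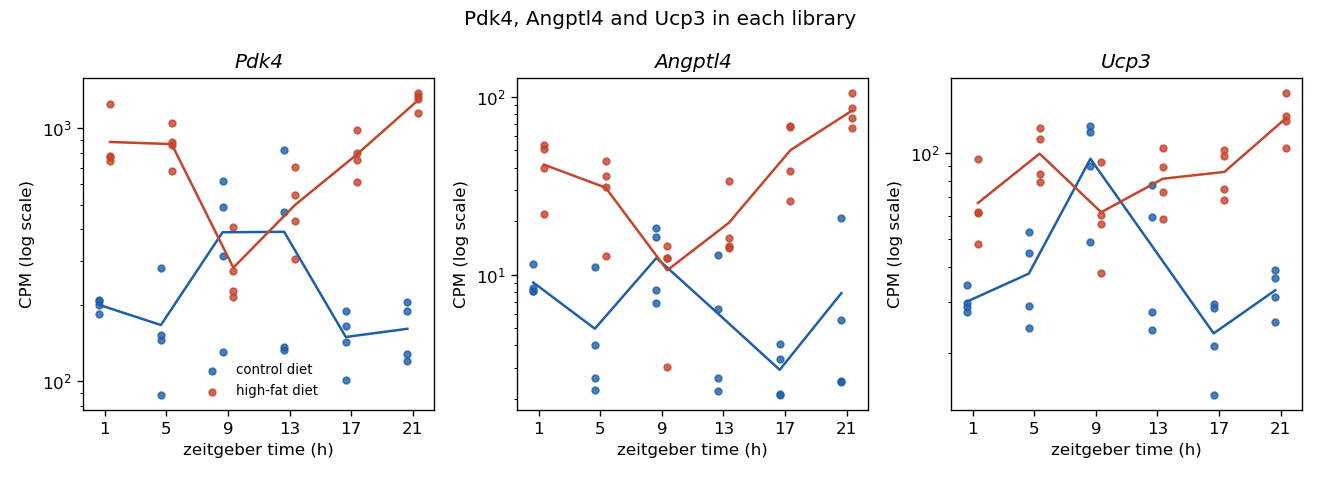
Pdk4, Angptl4 and Ucp3 in each library (points; lines join the means of 4 libraries) against zeitgeber time in hours, with CPM on a log scale, for control (blue) and high-fat (red) hearts. At ZT21 the diets stand apart (Pdk4 at 161 and 1292 CPM on average), and at ZT9 their points overlap (388 and 281 CPM).

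By gene list, the core clock was rhythmic in both diets, with 18 of 19 genes called in each (Fisher's exact test, adjusted p = 1.8e-13 in control and 8.6e-18 in high fat). Rora was the exception (0.09 and 0.12). Amplitudes in control and high fat were 0.50 and 0.48 for Clock, 0.88 and 1.04 for Npas2, 0.69 and 0.53 for Cry1 and 0.54 and 0.43 for Cry2. They were 0.85 and 0.80 for Nr1d2, 0.78 and 0.80 for Tef, 0.72 and 0.83 for Hlf, 1.08 and 0.93 for Nfil3, 0.61 and 0.79 for Bhlhe40, and 0.48 and 0.49 for Bhlhe41. Extracellular matrix genes peaked in ZT0-12: 15 of 24 were called in control and 14 in high fat (adjusted p = 8.0e-07 and 5.9e-09). Over all 48 libraries the score of endothelial markers also cycled (amplitude 0.14 ± 0.01, SE), and that of fibroblast markers had an amplitude of 0.06 ± 0.03. Examples of the matrix genes were the fibrillin gene Fbn1 (0.69 and 0.70), the collagen genes Col3a1 (0.69 and 0.56) and Col6a3 (0.51 and 0.37) and the elastin gene Eln (0.58 and 0.62). Of the heat shock and chaperone genes 10 of 14 were called in control and 7 in high fat (adjusted p = 1.3e-05 and 3.5e-04), such as Hspa8 (0.30 and 0.17) and Chordc1 (0.34 and 0.21). Their fitted peaks lay in ZT12-24. In control 1 of 14 passed as higher in ZT13-21 than in ZT1-9 and 0 as lower, with a list median of 0.06 log2. The highest list score was in control_ZT1 1 (7.40, against 6.36 to 6.46 in the other 3 libraries there). Glucocorticoid-responsive genes were called in 7 of 10 and 8 of 10 cases (adjusted p = 5.3e-04 and 6.9e-07), such as Fkbp5, which binds the hormone receptor complex (1.04 and 0.84), and the cell cycle inhibitor gene Cdkn1a (0.75 and 0.75). Of the endoplasmic reticulum stress genes 12 of 17 were called in control (adjusted p = 1.7e-06) and 3 of 17 in high fat (0.42), with Herpud1 at 0.69 and 0.57. That contrast was not tested at list level, and none of its genes passed the test for a different rhythm. Respiratory chain genes were called less often than other genes in control (1 of 66, adjusted p = 0.0059), and 1 of 66 was called in high fat (0.237). Their estimated correlation was 0.69, and Fisher's test takes genes as independent, so a true lack of rhythm in this list is not shown. Adjusted over the list alone, the called genes were 18 and 18 for the clock, 16 and 14 for the matrix, 11 and 8 for heat shock, 9 and 9 for glucocorticoid response, 13 and 7 for endoplasmic reticulum stress and 0 and 0 for the respiratory chain. No other list passed in either diet.

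The next question was what the high-fat diet changes over the whole day. The acyl-CoA thioesterase gene Acot1, of fatty acid metabolism, rose by 1.13 ± 0.11 log2 and the nicotinic receptor subunit gene Chrna2 by 1.65 ± 0.17 (SE, 24 against 24 libraries). Others were the endothelin gene Edn3 (1.30 ± 0.11), the phosphodiesterase gene Pde11a (1.27 ± 0.16) and the sodium channel subunit gene Scn4b (1.11 ± 0.09). Next came Mthfd2 of mitochondrial folate metabolism (1.10 ± 0.09) and Snhg11 (1.00 ± 0.18). Also higher were the potassium channel gene Kcnj14 (0.90 ± 0.13), Amph (0.87 ± 0.09), the erythropoietin receptor gene Epor (0.87 ± 0.10) and Lrrc36 (0.87 ± 0.12). Among the genes named here that moved the same way at all 6 times, the largest fall was in Scd1, at -1.44 ± 0.25. Scd1 makes monounsaturated fatty acids (ENSMUSG00000037071.3, chromosome 19, 44394455 to 44407879). The fatty acid synthase gene Fasn was at -0.92 ± 0.17. Lrrc4b, a synaptic adhesion gene (ENSMUSG00000047085.14, chromosome 7, 44429018 to 44463351), was at -1.20 ± 0.09. It was followed by Scgb1c1 (-1.02 ± 0.17), Lgi3 (-0.90 ± 0.10), the G protein subunit gene Gnb3 (-0.87 ± 0.12) and Dnph1 (-0.79 ± 0.11). Lower too were the GABA transaminase gene Abat (-0.77 ± 0.11), Bmp7 (-0.77 ± 0.12), the synaptic vesicle gene Sv2a (-0.75 ± 0.09), Hsbp1l1 (-0.74 ± 0.09) and the glycine methyltransferase gene Gnmt (-0.73 ± 0.11). Each of these genes moved the same way at all 6 times. edgeR adjusted p was 1.4e-11 for Scn4b, 3.6e-12 for Lrrc4b, 8.8e-05 for Scd1 and 1.3e-04 for Fasn. In all, 792 genes were higher and 748 lower with high fat, 1158 of them (75.2%) in the same direction at all 6 times, and 43 changed over 2-fold (33 higher, 10 lower). Within the 3 runs of titles (13, 21 and 14 libraries), tested alone, 625, 874 and 117 genes were called. There 98.7, 100 and 99.1% of the pooled genes moved in the pooled direction, which is partly built in, since they were called on the same libraries.

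PPAR-alpha targets, which take up, bind and burn fatty acids, rose as a list: 16 of 18 were higher and 0 lower (camera adjusted p = 3.9e-33, and adjusted p = 4.7e-06 with an estimated correlation). Beside Acot1, Pdk4 rose by 1.63 ± 0.17, Angptl4 by 2.30 ± 0.23, Ucp3 by 1.10 ± 0.13 and the thioesterase gene Acot2 by 0.73 ± 0.06 log2. Cpt1b (0.28) and Acsl1 (0.11) did not pass. Mitochondrial beta-oxidation followed, with 10 of 16 higher (adjusted p = 6.0e-19, and 0.0055 with an estimated correlation), such as Decr1 (0.44 ± 0.04), Cpt2 (0.40 ± 0.04), Hadha (0.32 ± 0.03) and Etfdh (0.30). Glucose uptake and glycolysis went down, with 11 of 25 lower and 1 higher (adjusted p = 2.4e-07, and 0.0119 with an estimated correlation). The insulin-regulated glucose transporter gene Slc2a4 was at -0.25 ± 0.03, the enolase gene Eno3 at -0.36 ± 0.05 and Gpi1 at -0.19, while Pfkl rose by 0.18. Cardiomyocyte markers were also lower, with a list median of -0.20 log2 against -0.11 for glycolysis. Of the fatty acid synthesis genes, 7 of 15 were lower and 2 higher (adjusted p = 0.0131, and adjusted p = 0.487 with an estimated correlation), with Acaca, the first committed step, at -0.66 ± 0.09 and the malic enzyme gene Me1 at 0.35. White adipocyte markers had a list median of -0.13 and did not pass (adjusted p = 0.765), with Cfd at -1.10 ± 0.32. The libraries control_ZT1 3 and control_ZT17 2 had the highest scores of both lists (5.22 and 5.06 for synthesis, 2.64 and 2.40 for adipocytes). In triglyceride synthesis and lipid droplets 7 of 20 rose and 2 fell (adjusted p = 0.0131 upward, and 0.287 with an estimated correlation, with a list median of -0.01 and a mean of 0.07). Gpam, which starts glycerolipid synthesis, rose by 0.60 ± 0.06 and the lipase gene Lipe by 0.45, and Plin3 was at -0.28. Smaller shifts that passed with the preset correlation alone were glycogen metabolism (4 of 13 lower, 1 higher; adjusted p = 0.0218, estimated 0.497; Ppp1r3b -0.35), branched-chain amino acid catabolism (3 of 20 lower; 3.6e-04, estimated 0.287; Bckdhb -0.26) and the respiratory chain (3 of 66 lower; 0.0030, estimated 0.753; Sdhd -0.14). Respiratory chain scores also ran high in the 7 libraries of lowest title number, which both diets hold. Adjusted over the list alone, the genes higher and lower were 16 and 0 for PPAR-alpha targets, 13 and 1 for beta-oxidation, 4 and 13 for glycolysis, and 2 and 8 for fatty acid synthesis. They were 8 and 3 for triglycerides, 2 and 6 for glycogen, 0 and 4 for branched-chain catabolism and 0 and 2 for the respiratory chain.

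**Figure D3:**
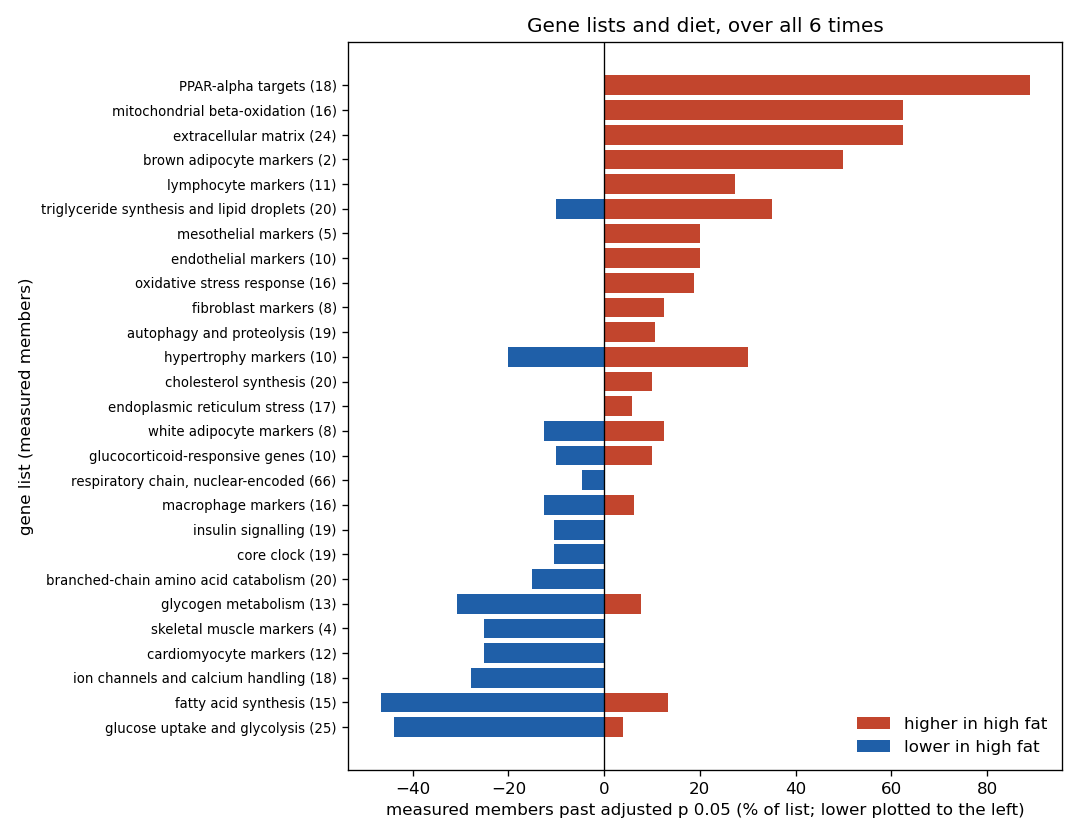
Share of each list's tested genes (number in parentheses) that passed an adjusted p of 0.05 for the diet effect over all 6 times, in % of the list, with genes higher in high fat to the right (red) and lower ones to the left (blue). PPAR-alpha targets lead on the right (16 of 18), and fatty acid synthesis (7 of 15) and glycolysis (11 of 25) reach furthest to the left.

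Extracellular matrix genes rose with high fat, 15 of 24 higher and 0 lower (camera adjusted p = 6.0e-16, and 0.0138 with an estimated correlation), among them the matricellular gene Postn (0.45 ± 0.06), Col6a3 (0.42 ± 0.05), Col3a1 (0.38 ± 0.06) and Col6a2 (0.28). Markers of several cell types moved beside them. Cardiomyocyte markers fell (3 of 12 lower; adjusted p = 2.3e-05, estimated 0.0121), with Mybpc3 and Tnnt2, both of the sarcomere, at -0.27 ± 0.05 and Actc1 at -0.22. Endothelial markers rose (2 of 10 higher; 0.00102, estimated 0.0055), with the tight junction gene Cldn5 at 0.48 ± 0.09 and the fatty acid chaperone gene Fabp4 at 0.34 ± 0.07. Fibroblast markers were higher with the preset correlation alone (1 of 8; 0.00102, adjusted p = 0.249 with an estimated correlation), with Lum at 0.40 ± 0.06. Macrophage markers did not pass (1 higher and 2 lower of 16; 0.765). Ion channels and calcium handling genes passed with the preset correlation (5 of 18 lower; 0.0023, estimated 0.323), with the potassium channel genes Kcnip2 at -0.34 ± 0.04 and Kcnq1 at -0.27 and the pacemaker channel gene Hcn2 at -0.30. The core clock list did not pass (2 of 19 lower; 0.0651), with Ciart at -0.45. Adjusted over the list alone, genes higher and lower were 20 and 1 for the matrix, 0 and 7 for cardiomyocytes, 3 and 0 for endothelium, 4 and 0 for fibroblasts, 1 and 2 for macrophages, 0 and 5 for ion channels and 0 and 2 for the clock.

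The diet effect was then read at each time of day. Early in the light phase Pdk4 was already raised, by 2.14 ± 0.41 log2 at ZT1 and 2.38 at ZT5, with Chrna2 (1.86 and 2.54) and Angptl4 at ZT5 (2.58 ± 0.59). Lrrc4b was at -1.59 and -1.17, Lgi3 and Sv2a at -1.26 each at ZT1, and Pde1c and Mlf1 at -0.54 and -0.46 at ZT5. At ZT9 Pdk4 was not called (-0.46, adjusted p = 0.999), and the 2 called genes were the slow troponin gene Tnnt1 (-0.76 ± 0.15) and Tceal8 (-0.68 ± 0.10). At ZT13 Edn3 (1.82 ± 0.29), Mthfd2 (1.08) and the vesicular glutamate transporter gene Slc17a7 (1.07) were highest, and Abat (-1.35), Gnb3 (-1.26) and Gnmt (-1.25) lowest. Of the genes named at ZT17 and ZT21, Angptl4 rose by 4.16 ± 0.63 at ZT17 and 3.45 ± 0.58 at ZT21, Pdk4 by 2.39 and 3.00 ± 0.43, Chrna2 by 2.23 at ZT17 and Ucp3 by 2.002 ± 0.31 at ZT21. Lrrc4b (-1.33), Dnph1 (-1.31) and Lgi3 (-1.20) were lowest at ZT17, and the macrophage gene Gpnmb (-2.40 ± 0.59), the natriuretic peptide gene Nppb (-1.93 ± 0.43) and Lrrc4b (-1.50 ± 0.23) at ZT21 (SE, 4 against 4 libraries). In 30 of the 32 cases that the naming rule gives all 4 high-fat libraries lay beyond all 4 control libraries. These genes were chosen for the size of the change between the same libraries, so that the 2.86% that chance gives for a gene not so chosen is no test of them. The exceptions were Lgi3 at ZT17, with 3 of 4 high-fat libraries below all control libraries, and Gpnmb at ZT21, with 0 of 4. For Gpnmb all 4 lay below the control mean.

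The numbers of genes higher and lower in high fat were 46 and 25 at ZT1, 39 and 4 at ZT5, 0 and 2 at ZT9, 21 and 18 at ZT13, 66 and 65 at ZT17 and 88 and 23 at ZT21 (edgeR, 4 against 4 libraries). With DESeq2 they were 80 and 78 at ZT1, 56 and 19 at ZT5 and 14 and 9 at ZT9. At ZT13, ZT17 and ZT21 DESeq2 gave 70 and 51, 112 and 120, and 123 and 47. With the share of reads in no gene as a covariate they were 97 and 97 at ZT1, 62 and 18 at ZT5 and 3 and 6 at ZT9. At ZT13, ZT17 and ZT21 that covariate gave 95 and 61, 104 and 85, and 216 and 183. Whether these numbers differ between times was not tested. Single libraries moved them. The ZT1 count was 42, 24, 34 and 19 without control_ZT1 2, control_ZT1 3, highfat_ZT1 3 and highfat_ZT1 4. The ZT5 count was 20, 6, 24 and 14 without control_ZT5 2, control_ZT5 4, highfat_ZT5 1 and highfat_ZT5 3. The ZT13 count was 61, 20, 7, 22, 23, 74, 77, 72, 24, 6, 15 and 69 without control_ZT1 4, control_ZT13 1, 2, 3 and 4, control_ZT21 1 and 4, highfat_ZT1 3, highfat_ZT13 2, 3 and 4 and highfat_ZT17 1. The ZT17 count was 79, 56, 57, 51 and 83 without control_ZT17 1, 2 and 3 and highfat_ZT17 1 and 4. The ZT21 count was 57, 53, 48, 58 and 70 without control_ZT21 2 and 3 and highfat_ZT21 1, 3 and 4. The Tnnt1 call at ZT9 was lost in 32 of the 48 fits without 1 library, and Gpnmb lost its call at ZT21 in 7 of 11 alternatives.

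Finally, ZT13, 17 and 21 were set against ZT1, 5 and 9, the contrast closest to night against day. In both diets glucocorticoid-responsive genes were higher in ZT13-21 (5 of 10 and 0 lower in each), with Fkbp5 at 1.35 log2 in control and 1.18 in high fat and Zbtb16 at 1.31 and 1.14. Camera adjusted p was 1.1e-12 in control and 1.1e-15 in high fat, and 0.00201 and 4.2e-04 with an estimated correlation. Extracellular matrix genes were lower (13 of 24 in control, 11 in high fat, 0 higher), with Col3a1 at -0.85 and -0.71 and Fbn1 at -0.78 and -0.80. Adjusted p was 3.1e-19 and 9.8e-21, and 0.0144 and 0.0096 with an estimated correlation. Core clock genes went both ways, 7 higher and 7 lower in control and 7 and 6 in high fat, with Nr1d1 at -1.59 and -1.95 and Per2 at 1.02 and 1.11. In all, 730 genes passed in control (385 higher, 345 lower) and 479 in high fat (236 higher, 243 lower). The test of the difference between the diets called 0 genes (edgeR; unadjusted p under 0.05 for 783, where chance would give 832; DESeq2 also called 0). Without the 7 libraries of lowest title number the high-fat count was 1190 and the control count 760. Adjusted over the list alone, genes higher and lower in control were 8 and 0 for glucocorticoid response, 0 and 16 for the matrix and 9 and 8 for the clock, and in high fat 8 and 0, 0 and 13, and 7 and 7.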

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

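The tests of diet labels, of the run of titles, of the 7 libraries of lowest title number, of smaller amplitudes and of cell shares were chosen only after the result was seen, as were the fits without single doubted libraries and the bound on length for diet labels, set after the first bound (0 of 16 libraries nearer to the other diet) was not met, and the tests of time labels, of the spread within groups and of regrouped libraries before.

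By fitted peaks Pdk4, Ucp3 and Angptl4 were high at different times of day in the diets, but only Pdk4 passed the test of a different rhythm, and neither Ucp3 in high fat nor Angptl4 in control passed as rhythmic (adjusted p = 0.443 and 0.456). Wrong time labels are argued against, since 0 of the 16 libraries at ZT9 and ZT13 lay nearest to a time 8 h or more from their label by the 19 clock genes, though highfat_ZT13 4 (Pdk4 at 305 CPM) lay nearest to ZT9, 4 h off, and without it the difference in rhythm of Pdk4 went from 1.52 ± 0.26 to 1.49 ± 0.26 log2 (SE; adjusted p = 0.112). A constant shift between the runs of titles as the whole cause is argued against. With the run as a covariate the differences were 1.49 ± 0.26 for Pdk4, 1.00 ± 0.22 for Ucp3 and 1.51 ± 0.33 for Angptl4 (highest unadjusted p 1.98e-04, edgeR). Without the covariate they were 1.52 ± 0.26, 1.05 ± 0.22 and 1.59 ± 0.35. With it the call of Pdk4 was lost at an adjusted p of 0.0553, close to the threshold on both sides. The covariate shifts all times of a run alike, so a daily course that differs between runs was not tested. In control at ZT13 Pdk4 was at 824 and 466 CPM in the libraries of run 2 and at 137 and 133 CPM in those of run 3. Within each run, tested alone, 0 genes passed for the difference in rhythm. Wrong diet labels as the whole cause are argued against too: 1 of the 16 libraries, control_ZT9 2 (Pdk4 at 622 CPM), lay nearer to the other diet and no high-fat library did, and without it the differences were 1.42 ± 0.26, 0.95 ± 0.22 and 1.45 ± 0.35, with the call of Pdk4 lost (adjusted p = 0.0835, within 0.00151 to 0.148 over all alternatives) as the length fell and the SE did not. A wrong label of that library alone stays open, and so, as a hypothesis, does a different daily course with diet, while feeding times, which the labels do not give, were not tested.

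Fewer genes were called rhythmic in high fat (1323) than in control (2301). A larger spread within high-fat groups is argued against, since the median SD within groups was 0.955 times that of control (0.236 and 0.248 log2). The 7 libraries of lowest title number may account for the order, since the high-fat count without them was 2236 against 2094 in control. Smaller amplitudes in high fat also stay open: the median difference was -0.03 log2 (-0.0284) over 4084 genes, smaller in high fat for 63.7% of them, and 3 of 100 regroupings of diet were as low (the lowest other was -0.0338). Chance cannot be excluded either, since 14 of 100 regroupings gave a difference between the counts as large as the real 978, the highest other being 1887.

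Extracellular matrix genes were higher in high fat (score difference 0.22 ± 0.04 log2, SE, 48 libraries) and peaked by day (amplitude 0.26 ± 0.03). A lower share of cardiomyocytes stays open. Fibroblast markers rose over macrophage markers by 0.15 ± 0.04 (0.147), past the bound of 2 SE set against this cause. But macrophage markers (-0.002 ± 0.06) had members moving both ways, 1 higher and 2 lower of 16, so that bound cannot decide. Fibroblast and endothelial markers rose alike (0.14 ± 0.04 and 0.15 ± 0.02), cardiomyocyte markers were at -0.16 ± 0.03, and mural markers at 0.04 ± 0.06. More fibroblasts cannot be told apart from a change within them, since the matrix rose over fibroblast markers by 0.08 ± 0.04 (0.0800), under 2 SE. A fibroblast share that changes over the day is argued against for the rhythm, since the matrix score minus the fibroblast score kept an amplitude of 0.22 ± 0.03 (0.217), but endothelial markers cycled too (0.14 ± 0.01), and a share of those cells that changes over the day was not tested. A change of transcription with diet and time of day stays open as a hypothesis.

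In 5 of 60 groups checked, 1 library stood apart from the other 3, where chance gives about 1 in 20 groups. Pdk4 was at 1244 CPM in highfat_ZT1 4 (the next at 774), Angptl4 at 11.5 CPM in control_ZT1 3 (8.40), at 20.9 CPM in control_ZT21 1 (5.54) and at 33.5 CPM in highfat_ZT13 3 (16.1), and Dbp at 6.34 CPM in highfat_ZT1 3 (8.30).

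The diets differed in the rhythm of Pdk4 (edgeR adjusted p = 0.0468). In the contrast of ZT13-21 against ZT1-9 they differed, with the preset correlation, in PPAR-alpha targets (camera adjusted p = 0.0184, median difference 0.07 log2), glucose uptake and glycolysis (0.0399, 0.06), the respiratory chain (9.7e-05, 0.10), mitochondrially encoded genes (0.0489, -0.16) and lymphocyte markers (0.0452, 0.57). None of these 5 lists passed with an estimated correlation (adjusted p = 0.781 for each). The 7 libraries of lowest title number, all at ZT21, ZT1 or ZT5, had higher scores of the respiratory chain (median 8.83 against 8.39) and of mitochondrially encoded genes (11.1 against 10.4).

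Regrouping the libraries argued against chance alone for 5 counts, since the real labels called the most genes. For rhythm these were control (2301, highest other of 100 regroupings 89) and high fat (1323, 1). The others were the diet effect over all times (1540, 1) and the contrast of ZT13-21 against ZT1-9 in control (730, 32) and in high fat (479, 13). The rank does not vouch for each gene called, and the regroupings took no account of the runs of titles. For the diet effect at ZT5 (43, highest other of 35 splits 0), ZT13 (39, 7), ZT17 (131, 2) and ZT21 (111, 37) the real split called the most genes. With only 35 splits at each of 6 times, that rank cannot exclude chance at a single time. In fits of 1 time alone these 4 counts were 9, 0, 41 and 7. Without 1 library the count fell to as low as 6 at ZT5 and 6 at ZT13. At ZT9 the real split called 2 genes and the others 0. There, 0 were called without the 12 lower-depth libraries, and Tnnt1 was lost in 32 of the 48 fits without 1 library. DESeq2 shared 0 of the 2, but it gave an adjusted p to 3870 genes at ZT9, against 16642 in edgeR. Whether the 2 genes were among them is not given here, so the lack of overlap is not read either way. For the difference in rhythm 2 of 100 regroupings, the real one included, gave 1 gene or more, the highest other being 1. Chance was not excluded for the difference between diets in the contrast of ZT13-21 against ZT1-9 (real 0, 100 of 100 regroupings as large, highest other 1), nor at ZT1 (real 71), where 2 of 35 splits gave as many genes. The other split at ZT1 called 2437 genes and set highfat_ZT1 1, highfat_ZT1 2, control_ZT1 1 and control_ZT1 4 against the rest, which points to a structure of the samples, since these 4 had more reads in no gene (4.25, 5.06, 4.59 and 5.85%) than the other 4 at ZT1 (3.42 to 3.71%), and the first 3 are among the 7 libraries of lowest title number. The ZT1 count was 116 with the run of titles as a covariate (64 higher, 52 lower, 71 of 71 shared). Without the 7 libraries it was 101, of which 34 were shared, and the balance turned from 46 higher and 25 lower to 38 higher and 63 lower.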

How the results depend on the processing

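The covariates for lower depth, reads in no gene, atrial markers and the residual component, and the fits without 12 or 7 libraries, were chosen only after the data were seen. The cause of each change below was not tested, except that fits of fewer libraries, and fits without 12 or 7, hold fewer samples. The residual component was estimated from the same residuals, so its p-values are too small. No paired analysis was possible because the labels carry no replicate numbers.

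The control rhythm (2301 genes) stayed within 1.5 times its count under every alternative but the residual component (4414). The high-fat rhythm (1323) was 855 in a test of any difference between the 6 times, 3536 with the residual component and 2236 without the 7 libraries. The diet effect over all times (1540) was 2314 with the share of reads in no gene and 3084 with the residual component, and all 1540 genes were shared with each. The contrast of ZT13-21 against ZT1-9 in control (730) was 485 with no filter and 1802 with the residual component. In high fat (479) it was 307 with no filter, 778 with the run of titles, 765 with reads in no gene, 1539 with the residual component, 283 without the 12 lower-depth libraries and 1190 without the 7. Its difference between diets (0) was 96 with the residual component, 1 without the 12 and 1 without the 7. The difference in rhythm (1) was 5 with DESeq2, 3 in the test of any difference, 4 with reads in no gene, 11 with the residual component, and 0 with no filter, the run of titles, atrial markers, without the 12 and without the 7.

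At single times the counts at ZT1, ZT5, ZT9, ZT13, ZT17 and ZT21 were 71, 43, 2, 39, 131 and 111. With DESeq2 they were 158, 75, 23 (0 shared, with 3870 genes given an adjusted p at ZT9), 121, 232 and 170. With the residual component they were 601, 117, 54, 354, 1226 and 404, and in fits of 1 time alone 8, 9, 15, 0, 41 and 7. With the run of titles they were 116 at ZT1, 66 at ZT5, 109 at ZT13, 285 at ZT17 and 177 at ZT21. With reads in no gene they were 194 at ZT1, 80 at ZT5, 9 at ZT9, 156 at ZT13 and 399 at ZT21. With no filter they were 25 at ZT13, 73 at ZT17 and 66 at ZT21. With atrial markers they were 1 at ZT9 and 77 at ZT13, and with RLE scaling 1 at ZT9. Without the 12 libraries they were 10 at ZT1, 1 at ZT5, 0 at ZT9 and 48 at ZT17, and without the 7 they were 18 at ZT5, 5 at ZT9, 78 at ZT13, 212 at ZT17 and 63 at ZT21. The lower-depth covariate kept all 13 counts within 1.5 times.

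Leaving out each of the 48 libraries gave 0 to 5 genes for the difference in rhythm (5 without control_ZT21 1), 0 to 1 for the difference between diets in the contrast of ZT13-21 against ZT1-9 (1 without highfat_ZT17 1). They gave 19 to 83 at ZT1, 6 to 52 at ZT5, 1 to 4 at ZT9, 6 to 77 at ZT13, 51 to 188 at ZT17 and 48 to 127 at ZT21. The other counts stayed within 1.5 times: 1981 to 2634 for the control rhythm, 1111 to 1422 for the high-fat rhythm, 1406 to 1659 for the diet effect, and 582 to 952 in control and 376 to 566 in high fat for the contrast. With an estimated correlation 6 of 14 lists kept their call for the diet effect, 2 of 9 and 2 of 10 for the contrast in control and high fat, and 0 of 5 for its difference between diets.

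Of 563 values of named genes 307 were called: 206 kept the call under every alternative and left-out library, 101 lost it in at least 1 other alternative and 58 without at least 1 library, and 0 called values were reversed. What depth alone limits was not tested, since leaving out the 12 libraries at 11.2 to 19.9 M counts also removes samples.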

Other observations

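Of 11 lymphocyte markers 3 were higher in high fat over all times, or 5 adjusted over the list alone, among them Ms4a1 at 0.88 ± 0.25 log2 and Cd79b at 0.60 ± 0.18 (SE, 24 against 24 libraries). The list passed with the preset correlation (camera adjusted p = 0.0152, and adjusted p = 0.497 with an estimated correlation). Its levels were low, with scores from -1.31 mean log2 CPM in control_ZT17 4 to 1.15 in highfat_ZT21 1. The next highest score was 0.44 in highfat_ZT17 1. Of 16 macrophage markers 13 did not pass, nor did the list (0.765). Ccr2, a receptor of recruited monocytes, rose by 0.43 ± 0.10, and Timd4 and Lyve1, both of resident macrophages, were at -0.34 ± 0.08 and -0.24 ± 0.07. Globin genes were higher in ZT13-21 than in ZT1-9 in high fat (3 of 5 erythroid markers, 5 adjusted over the list alone: Hba-a2, Hbb-bt at 1.56 and Hbb-bs at 1.37). The list passed with the preset correlation (camera adjusted p = 3.8e-04, adjusted p = 0.376 with an estimated correlation). In control Hbb-bt was at 0.86 and Hbb-bs at 0.80, with 0 of 5 called, and the difference between diets did not pass (adjusted p = 0.375). The erythroid score ran from 4.90 mean log2 CPM in highfat_ZT13 2 to 9.80 in control_ZT13 2, and the share of red blood cells was not measured.

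Other lists did not pass for the diet effect, though single members did. The catalase gene Cat rose by 0.41 ± 0.05, Srxn1 by 0.22 and Nqo1 by 0.23 (oxidative stress response, 3 of 16; camera adjusted p = 0.0635). Of 10 hypertrophy markers Xirp2 (0.22), Fhl1 (0.20) and Gdf15 (0.56) were higher and Nppb (-0.62 ± 0.17) and the slow myosin gene Myh7 (-0.23) lower (0.765). In insulin signalling Akt1 was at -0.34 ± 0.03 and Akt2 at -0.09 (2 of 19; 0.0522). Glucocorticoid-responsive genes had Fkbp5 at -0.40 and Sgk1 at 0.22 (0.130), cholesterol synthesis Insig1 at 0.29 and Dhcr7 at 0.19 (0.186, with a list median of -0.09). In autophagy and proteolysis Bnip3 was at 0.23 and Sqstm1 at 0.14 (0.765), in endoplasmic reticulum stress Trib3 at 0.30 (0.801), white adipocytes Adig at 0.62 and Cfd at -1.10 (0.765), mesothelium Wt1 at 0.27 (0.669) and skeletal muscle Tnni2 at -0.49 (0.254). In the brown adipocyte list, too short to test, Cidea was at 0.33, and no lung epithelium marker was expressed well enough to be tested. No gene was called (edgeR) among interferon response (0.0518), mitochondrially encoded genes (0.186), immediate early genes (0.222), neutrophils (0.314), atrium (0.563, downward, with a list median of -0.02 and a mean of 0.28), heat shock (0.765), mural cells (0.765) and erythroid cells (0.958). The libraries were not alike in atrial markers. Their score ran from 0.36 mean log2 CPM in control_ZT5 4 to 8.58 in highfat_ZT17 2, and was 2.63 in highfat_ZT17 1. In high fat the atrial list mean was 1.32 log2 higher in ZT13-21 than in ZT1-9, which did not pass (camera adjusted p = 0.0631).

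In the contrast of ZT13-21 against ZT1-9 further lists passed with the preset correlation alone. In high fat these were the respiratory chain (camera adjusted p = 8.2e-06, estimated 0.621), heat shock (1.0e-04, 0.259), triglyceride synthesis (1.8e-04, 0.117), glycolysis (3.8e-04, 0.147), beta-oxidation (0.00118, 0.498), glycogen (0.00377, 0.498) and branched-chain catabolism (0.0308, 0.591), all upward. In control they were branched-chain catabolism (0.00105), glycogen (0.00326) and insulin signalling (0.0261) upward and lymphocytes (0.00341) and neutrophils (0.0371) downward (adjusted p = 0.477 with an estimated correlation for each), with mesothelium downward (0.0371, 0.509) and erythroid markers upward (0.0471, 0.624).

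Some genes abundant in the heart had almost no counts. Over all 48 libraries Atp5a1 had 31 counts, Uqcrc1 22, Pygm 5, Ndufs3 5, Hspa4l 3 and Fbxo32 2, each in a run of neighbouring genes that were all low. Pygm lay in a run of 13 such genes on chromosome 19 (6184388 to 6544169, GRCm38), 9 of them with no count, and Fbxo32 in a run of 9 on chromosome 15 (57985419 to 58457740), 7 with no count. Of 432 pathway genes 9 had under 1 count per library on average, against 30.6% of 21974 protein-coding genes. On the mitochondrial chromosome mt-Co1 was at 98474 CPM and mt-Cytb at 54952 CPM, but mt-Co2 at 12.2, mt-Co3 at 8.36, mt-Atp6 at 4.54 and mt-Atp8 at 0.0293 CPM. These genes are therefore missing from, or near the floor in, the lists they belong to.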
